A study of Caenorhabditis elegans with 2 samples.

How the data were processed

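ChIP-seq of eGFP-tagged BLMP-1 was measured in 2 biological replicates of mixed-stage C. elegans embryos, which form 1 group per the labels. The deposited files used here are peak lists in narrowPeak form on builds ce10 and ce11: the authors' optimal IDR list, the pooled candidate list, and a candidate list for each replicate. The aligner, the peak caller and the IDR threshold were not given in the sources used here. The labels list a possible control experiment, which was not analysed here. Signal tracks and alignments were not used here. Strength is the authors' signal value per region, a score whose scale and normalization the deposited files do not state, so signal values were not compared in size between lists. The other strength column of the deposited lists is the -log10 q value by the narrowPeak convention, which reached its ceiling in 93.6% of the IDR peaks, 1.22% of replicate 1's candidates and 4.84% of replicate 2's, and was used in 1 alternative only. The other column used is the summit offset in bp, per the deposited lists. Several summits can share a region, so the 843 peaks occupy 838 distinct regions.

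Summits were placed on the ce11 genome (WBcel235) with the Ensembl release 115 annotation and RefSeq gene names, and positions are 1-based. No position was converted between builds. A promoter window ran from 2000 bp upstream to 500 bp downstream of the start of a protein-coding gene, and summits were assigned in the order promoter, exon, intron, other. A gene counted as bound when its window held an IDR summit. The background for genes was the 11025 of 19985 protein-coding genes with a pooled candidate region in the window, and for peaks the 29092 pooled candidates that overlap no IDR peak. Sequences were searched on both strands, wholly within 50 bp of the summit.

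Shares were compared by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment within each family (4 location classes, 6 sequences, 19 gene lists) and a threshold of 0.05. Intervals of shares are exact (Clopper-Pearson), and those of odds ratios use the log scale with a continuity correction. Replicates were compared by the share of each one's 843 strongest regions that overlap the other's by at least 1 bp, with 1000 seeded random draws for chance. No paired analysis was possible because there is a single group, and no split of the samples into groups was possible with 2 samples. The read depth is unknown, so no interval or limit that needs it was given. The gene list test was tested on simulated data with 200 sets of 60 genes drawn from the 11025 genes: it called 1% of sets drawn without preference, 84% with bound genes drawn at weight 3 and 100% at weight 5, at an unadjusted p under 0.05. Most lists were smaller, down to 11 tested genes, and were called at adjusted p, so these rates do not hold for them.

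The gene lists were cuticle collagens, apical matrix and molting, hedgehog-related and patched-related, heterochronic, epidermal transcription factors, epidermal junctions and morphogenesis, intestine, body wall muscle, pharynx, neuronal, axon guidance and cell migration, Wnt signalling, BMP signalling and body size, germline and oocyte, cytosolic ribosomal proteins, histones, nuclear hormone receptors, homeobox, and heat shock and stress. These lists, the tests and the rule for named genes were fixed before the data were examined. The rule names the genes at the 15 strongest IDR peaks, up to 4 bound members of each list by peak signal (8 where the list passed), 13 genes whatever their value (blmp-1, unc-119, bed-3, lin-29, dre-1, lin-4, let-7, lin-28, nhr-23, nhr-25, elt-1, elt-3 and unc-5), the genes at the 5 highest regions of each replicate alone, and the 5 genes with the most IDR summits. The miRNA genes of the heterochronic list were fixed as values apart from its test. Other genes are named as chosen after their values were seen. The value given for a list member is the signal of the strongest IDR peak in its window.

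Alternatives covered the 422 strongest IDR peaks, each replicate's own 843 strongest regions in place of the IDR list, the 14546 other candidates of lowest signal as background, the ce10 lists, promoter windows of 1000 bp upstream to 200 bp downstream and of 5000 bp upstream to 500 bp downstream, the nearest gene start alone, all protein-coding genes as background, and 10000 random gene sets matched on upstream length. The alternatives with a replicate's own regions changed the background as well as the peak set, so their shifts cannot be put down to the peaks alone. For sequences they covered 100 and 150 bp around the summit, a core of 7 letters and a background matched on G+C content with up to 10 candidates per peak. For noncoding RNA genes a distance of 200 bp was tried. For the replicates they covered a reciprocal overlap of 50%, summits within 100 bp, ranking by q value, and other list lengths. Nuclear chromosomes only, and the IDR list without the peaks in runs of replicate 1 regions that have no counterpart in replicate 2, were added after seeing the data. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.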

Results

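BLMP-1 is a zinc finger transcription factor of Caenorhabditis elegans and the homologue of vertebrate PRDM1. Its genomic sites were mapped by ChIP-seq through an eGFP tag in whole mixed-stage embryos of pooled sexes. The strain carries an integrated tagged blmp-1 transgene in an unc-119 mutant background. There was 1 group of 2 biological replicates, with a fragment size range of 150 to 350 bp in each. The authors' optimal list by IDR (irreproducible discovery rate) held 843 peaks on genome build ce11. The pooled list and each replicate's list held 30000 candidate regions. These lists give no read counts, so the depth of each library is unknown. The 95% intervals cover counting error only, and p-values are across peaks or genes, which are not replicates. With 1 group and no second condition, IDR peaks were compared with 29092 pooled candidate regions that overlap no IDR peak, and the replicates with each other.

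The strongest nuclear peaks included peaks upstream of atf-2, bcl-11, atf-8 and lpr-4, a gene for a lipocalin-related protein. The highest nuclear signal value was 722, at II 8750969 to 8751361, with its summit 838 bp upstream of atf-2, which encodes a bZIP transcription factor. Another peak of signal 540 had its summit at II 8749342, 2644 bp upstream of the same gene. That summit lay in no promoter window and 2092 bp outside its nearest protein-coding gene, mak-1. The peak at V 6354386, signal 507, lay 1639 bp upstream of bcl-11, a zinc finger gene. The peak at V 6105600, signal 391, lay 7 bp upstream of atf-8, another bZIP gene. The peak at X 15310380, signal 409, lay in an intron of the nuclear hormone receptor gene nhr-91. At I 1273939 a peak of signal 374 lay 906 bp outside its nearest protein-coding gene, Y48G8AR.8, and 5784 bp upstream of grh-1, which encodes the epidermal factor Grainyhead. The peak at X 11065015, signal 351, lay 111 bp upstream of lpr-4. The other 8 of the 15 strongest peaks lay on the mitochondrial genome, around CYTB, COX1, COX2, COX3, ND3, ND4 and ND5, with signal up to 1013.5 at position 5596.

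Among the 15 strongest nuclear peaks, a set chosen after its values were seen, 8 had the BLMP-1 core sequence AAGTGAAA within 50 bp of the summit. In this set 7 summits lay in a promoter window and 5 in introns. The further members lay upstream of bcl-11 at V 6352561, near K08F9.4, nrde-4 and W03F8.4, and in introns of ztf-16, B0353.1, Y48G8AL.15 and kin-20. Each of the 15 ranked 37 or better in replicate 1 and 31 or better in replicate 2. Over all 843 peaks the median signal value was 65.5, with a range of 46.1 to 1013.5, and the median width was 316 bp. The peaks numbered 139 on chromosome I, 135 on II, 140 on III, 120 on IV, 172 on X and 25 on the mitochondrial genome, and V carried 13.3% of them. The 843 peaks were the 843 regions of highest signal in the pooled list, and on build ce10 the authors' list held 869. Comparisons of IDR peaks with other candidates thus set stronger pooled signal against weaker.

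The replicates placed many of the same regions at the top, including those at atf-2, bcl-11 and atf-8. Of the 843 strongest candidate regions of replicate 1, 445 overlapped one of the 843 strongest of replicate 2, which is 52.8% (49.4 to 56.2, Clopper-Pearson). In the other direction 446 did, which is 52.9% (49.5 to 56.3). Random draws of 843 regions from each whole list shared 0.833% on average and at most 2.02% in 1000 draws. The draws ignore signal, so they do not show what the shared ranking reflects. Over the whole lists, 27.8% of each replicate's candidates overlapped a candidate of the other. Among nuclear regions, the BLMP-1 core sequence was at 20.3% (16.5 to 24.5) of the 419 shared regions of replicate 1, and at 9.57% (6.86 to 12.9) of the 397 at the top of replicate 1 alone. For nuclear regions of replicate 2 these shares were 18.1% (14.5 to 22.1) of 420 and 7.61% (5.20 to 10.7) of 394. The core was most frequent at the strongest regions of the pooled list, and these contrasts were not separated from signal strength.

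Across the 809 IDR peaks with a candidate in both replicates, Spearman's rho of the signal values was 0.429, and over the 785 nuclear ones it was 0.384. This is a description across peaks within 1 pair of samples. Of the 843 IDR peaks, 655 lay at the top of replicate 1, 554 at the top of replicate 2, 430 at both and 64 at neither. No candidate overlapped 25 of them in replicate 2 and 9 in replicate 1. A place in the IDR list thus does not show that both replicates held the peak.

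**Figure D1:**
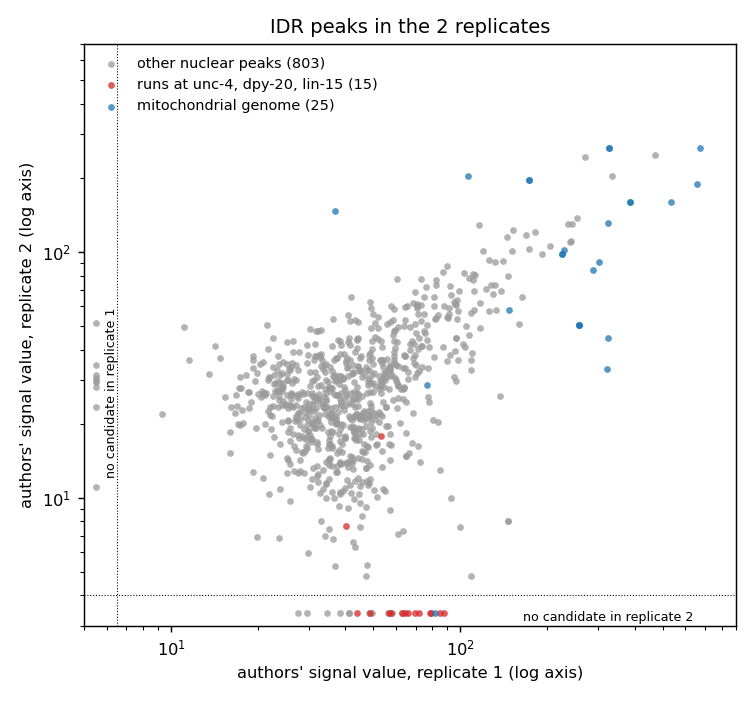
Authors' signal value of each IDR peak in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with peaks lacking a candidate in one replicate drawn at the edge of that axis. The 25 mitochondrial peaks and the 15 peaks at unc-4, dpy-20 and lin-15 are coloured, and 13 of those 15 have no candidate in replicate 2.

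Regions at the top of one replicate alone were led by different genes in each. In replicate 1 the highest lay in the promoter windows of ttr-39 and ttbk-5 (signal 146, rank 13043 in replicate 2), 27 bp outside nlp-18 (109, rank 29243) and upstream of mec-7, a beta-tubulin gene of touch neurons (99.8, rank 14521). The next lay in dpy-20 (93.1, rank 7863) and at the homeobox gene unc-4 (88.1, no candidate in replicate 2). In replicate 2, 3 of the 5 highest lay on the mitochondrial genome at 4499, 6157 and 8867, in the windows of CYTB, COX3, ND4, COX1 and COX2. The other 2 lay upstream of F33H1.4 (51.4, no candidate in replicate 1) and in daf-5 (50.6, rank 2089).

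Some of the replicate 1 regions stood in runs along single loci, a pattern chosen for description after its values were seen. Of the 93 nuclear top regions of replicate 1 with no candidate in replicate 2, 23 (24.7%) fell into 3 runs. The run at unc-4 held 7 regions from II 9897708 to 9902793, the run at dpy-20 held 6 from IV 11694934 to 11698731, and the run at lin-15B and lin-15A held 10 from X 15726047 to 15737556. Of the 105 such nuclear regions of replicate 2, none stood in a run. In the runs 10 of 23 summits (43.5%) lay in coding exons, against 0.955% of the 419 nuclear regions at the top of both replicates. The core was at 4.35% of the summits in runs. The regions in runs are neighbours at 3 loci, so no test is given.

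**Figure D2:**
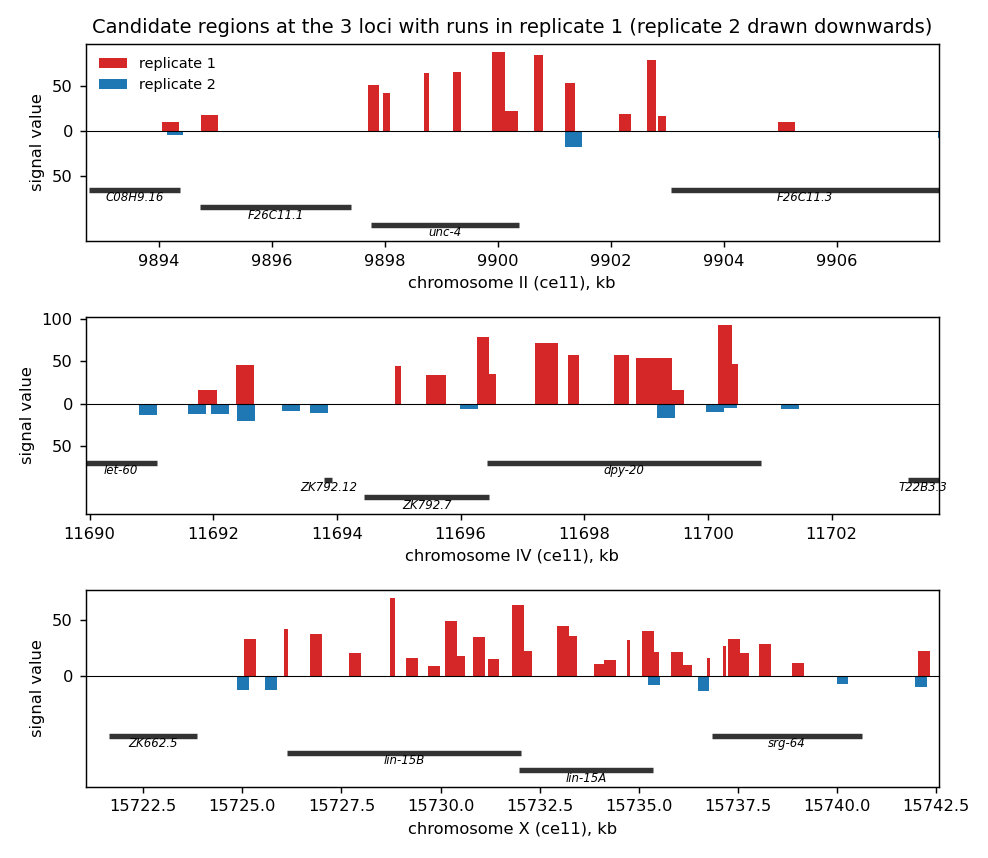
Candidate regions at unc-4, dpy-20 and lin-15 along each chromosome in kb on ce11, with the authors' signal value drawn upwards for replicate 1 and downwards for replicate 2, and genes as bars. The strongest regions without a candidate in replicate 2 have signal 88.1, 72.1 and 69.7 at the 3 loci.

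BLMP-1 peaks lay in promoters more often than the other candidate regions did, and in exons and introns less often. A promoter window, from 2000 bp upstream to 500 bp downstream of a protein-coding gene's start, held 489 summits, 58.0% (54.6 to 61.4), against 42.5% of the other candidates. The odds ratio was 1.87 (1.63 to 2.15), with adjusted p = 1.82e-18 by two-sided Fisher's exact test over 4 classes. This count includes summits on the mitochondrial genome, where the windows of neighbouring genes overlap. On nuclear chromosomes the windows held 467 of 818 summits, 57.1%, against 42.5% (odds ratio 1.80, 1.57 to 2.07). Exons outside promoters held 2.97% against 9.89% (odds ratio 0.278, 0.191 to 0.422, adjusted exact p = 5.63e-14). Introns held 20.3% against 28.4% (odds ratio 0.641, 0.542 to 0.761, adjusted exact p = 1.58e-07), while remaining positions held 18.7% against 19.2% (adjusted p = 0.756). By annotated feature alone, 65.4% of the summits were intergenic, against 43.5% of the other candidates. The median summit in a promoter lay at -466 bp from the start.

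The X chromosome carried 172 IDR peaks, 20.4% (17.7 to 23.3), against 18.3% of the other candidates. This difference did not pass the test (odds ratio 1.15, 0.968 to 1.36, two-sided Fisher's exact p = 0.125). It passed with nuclear chromosomes only (1.19, exact p = 0.0489). It also passed with replicate 1's own strongest regions in place of the IDR peaks, where the background changed too (1.21, exact p = 0.0247). The call for X thus rested on these choices.

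The sequence AAGTGAAA, the core bound by BLMP-1 and PRDM1, was far more frequent at BLMP-1 peaks than at other candidates, and most frequent at the strongest peaks. It lay within 50 bp of 127 summits, 15.1% (12.7 to 17.7), against 1.85% of the other candidates. A GAGAGA repeat lay at 252 summits, 29.9% (26.8 to 33.1), against 7.002%. Of the 818 nuclear peaks, 472 (57.7%) had neither sequence. At atf-2 the core stood at II 8751166 to 8751173, 22 bp from the summit, at lpr-4 it stood 19 bp away, and in the ztf-16 intron 2 bp away.

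By rank, the core was at 32.0% (23.02 to 42.1) of the 100 strongest nuclear regions, 10.3% (7.46 to 13.6) of ranks 401 to 800 and 1.496% (1.32 to 1.69) of ranks 12801 to 29974. GAGAGA was at 26% (17.7 to 35.7), 29.5% (25.1 to 34.2) and 5.58% (5.25 to 5.94) in the same bins. The core was more frequent at the 164 strongest nuclear IDR peaks than at the 163 weakest, with an odds ratio of 4.64 (2.35 to 8.64, two-sided Fisher's exact p = 1.44e-06). Core sites numbered 2.08 per kb within 25 bp of IDR summits and 0.208 per kb from 100 to 150 bp away, against 0.199 and 0.162 per kb around other candidates. In promoters 14.8% of 467 nuclear peaks had the core, in introns 16.4% of 171. No difference in core frequency between promoter peaks and the rest passed the test (odds ratio 0.876, 0.599 to 1.28, two-sided Fisher's exact p = 0.497).

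**Figure D3:**
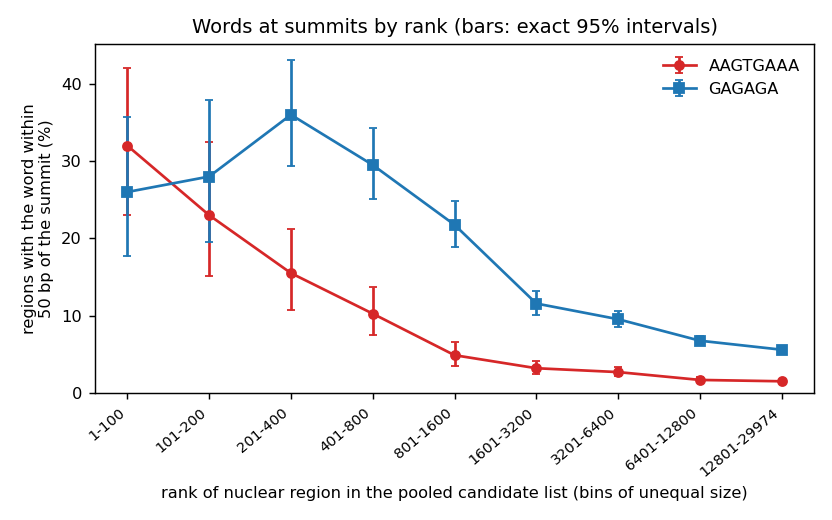
Share of nuclear regions (percent, vertical) with AAGTGAAA or GAGAGA within 50 bp of the summit, by rank in the pooled candidate list (horizontal, bins of unequal size), with exact 95% intervals. AAGTGAAA falls from 32.0% to 1.496%, and GAGAGA is highest, at 36.0%, in ranks 201 to 400.

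The odds ratio of the core was 9.43 (7.69 to 11.6), with adjusted p = 1.03e-67 by two-sided Fisher's exact test over 6 sequences, and that of GAGAGA was 5.66 (4.86 to 6.61, adjusted p = 1.18e-83). Among all 168 rearrangements of its letters the core had the highest share ratio, 8.16. The next, AAAGTGAA, which overlaps the core by 7 letters, had 7.84, and the median of the others was 1.42. The Sp1 word GGGCGG was at 5.81% against 1.97% (odds ratio 3.08, 2.30 to 4.18, adjusted exact p = 2.37e-10). The GATA factor word WGATAR (1.07, adjusted exact p = 0.440), the E-box CAGCTG (1.44, adjusted p = 0.149) and the AP-1 word TGASTCA (0.309, adjusted p = 0.149) did not pass. IDR summits had a median G+C content of 42.6% against 31.7%. Against other candidates matched on it, GAGAGA stood at 2.99 (adjusted exact p = 1.86e-35), Sp1 lost its call (1.33, adjusted p = 0.0821) and GATA gained one (1.31, adjusted p = 0.00621). The core stood at 10.4 with matching, and at 5.07 within 150 bp of the summit.

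The joint list of apical extracellular matrix and molting genes had BLMP-1 peaks in promoter windows more often than other genes. Of the 53 with a candidate region in the window, 14 had an IDR summit there, 26.4% (15.3 to 40.3), against 5.997% of the other genes. None of the list's mlt, nas or nekl genes was among the 14, so the result does not extend to them. The members lpr-3, lpr-4 and lpr-5 are neighbours on the X chromosome. The 8 with the highest signal were lpr-4 (351), lpr-3 (185), noah-2 (147), cutl-28 (137), noah-1 (118), cutl-14 (83.3), sym-1 (76.002) and let-653 (74.1). LPR-3, LET-653, NOAH-1 and NOAH-2 are components of the matrix that covers the embryo's outer epithelia or shapes the epidermis. Peaks at lpr-4, lpr-3, noah-2 and cutl-28 ranked 94 or better in the pooled list and among the 843 strongest of both replicates. Of the 14, 4 were not among the 843 strongest of one replicate: cut-2 (rank 15378 in replicate 1), lpr-5 (6267 in replicate 2), cutl-25 (3629 in replicate 2) and cut-6 (1746 in replicate 2), chosen after their values were seen.

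The odds ratio was 5.63 (3.13 to 10.6, adjusted p = 4.22e-05, two-sided Fisher's exact test over 19 lists). Over the alternatives that give an odds ratio it ranged from 4.58, with replicate 2's own regions, to 9.38 with the 422 strongest peaks, with adjusted exact p up to 0.00185. The count was 4.49 times the mean of random gene sets matched on upstream length (adjusted permutation p = 0.00380). A peak in the window had the core at 3 of the 14 genes, lpr-4, cutl-2 and cut-6, of which the latter 2 were chosen after their values were seen, and GAGAGA at 7. In all, 672 of 11025 genes with a candidate in the window had an IDR summit there.

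Genes of cytosolic ribosomal proteins also had peaks more often, at 12 of 63, 19.05% (10.2 to 30.9), against 6.02%. The highest signals were at rpl-3 (169), rpl-35 (115), rps-19 (69.9), rpl-12 (67.2), rps-28 (63.9), rps-20 (63.3), rpl-43 (59.6) and rpl-15 (58.6). By the same count as above, 5 of the 12 were not among the 843 strongest of one replicate. The genes rps-14 and rpl-36, chosen after their values were seen, share a peak of signal 50.5 that has no candidate in replicate 2. At none of the 12 genes did a peak in the window have the core or GAGAGA. Promoter signal common to many ChIP experiments could not be told apart from BLMP-1 binding at these genes. No other factor's peaks were used here. The odds ratio was 3.67 (2.03 to 7.06, adjusted p = 0.00341, two-sided Fisher's exact test). The call was lost with the 422 strongest peaks (2.37, adjusted exact p = 0.380) and with the nearest gene start alone (2.86, adjusted p = 0.157), and the odds ratio rose to 6.37 with replicate 2's own regions.

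**Figure D4:**
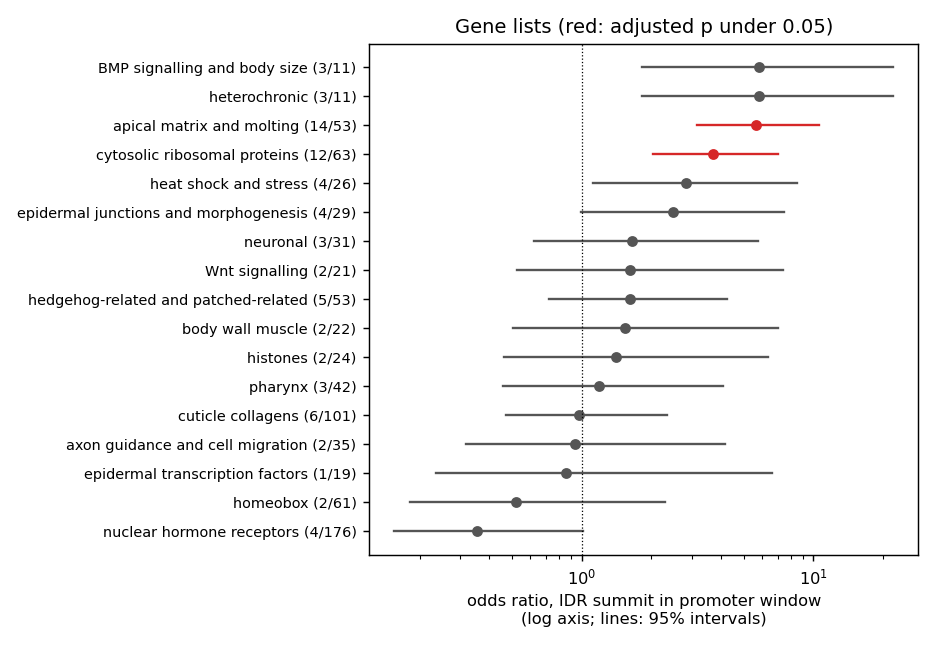
Odds ratio of an IDR summit in the promoter window for each gene list with a bound member (horizontal, log axis), with 95% intervals and the members bound and tested beside each name. Apical matrix and molting (14 of 53) and cytosolic ribosomal proteins (12 of 63), in red, pass the adjusted test.

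Other lists linked to the epidermis and to timing did not pass over the 19 lists. Heterochronic genes, which time larval development, had peaks at 3 of 11, nhl-2 (139), lin-41 (66.9) and ain-1 (49.95), with an odds ratio of 5.799 (1.83 to 22.1, exact p = 0.0257, adjusted p = 0.0987). BMP signalling and body size gave the same count of 3 of 11, at tig-2 (86.3), sma-3 (63.99, no candidate in replicate 2) and sma-1 (50.5), with the same odds ratio and p-values. Both passed with a window reaching 5000 bp upstream (7.90, adjusted exact p = 0.00791). With replicate 1's own regions the heterochronic odds ratio was 1.36 (adjusted exact p = 0.787), and the lin-41 peak ranked 8249 in replicate 1 and 173 in replicate 2. With the 422 strongest peaks the BMP odds ratio was 3.48 (adjusted exact p = 0.567). Epidermal junctions and morphogenesis had 4 of 29, at che-14 (165), spc-1 (124), hmp-2 (87.3) and sma-1 (2.47, 0.998 to 7.45, adjusted exact p = 0.264). That list passed with the 5000 bp window (3.54, adjusted exact p = 0.0287) and with replicate 2's own regions (4.73, adjusted p = 0.0489). Hedgehog-related and patched-related genes had 5 of 53, at ptr-10 (118), wrt-2 (66.4), ptr-1 (56.0), grl-15 (54.8) and ptr-2 (52.002, chosen after its value was seen), with an odds ratio of 1.61 and adjusted exact p = 0.539.

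Cuticle collagens had peaks at 6 genes, 5.94% (2.21 to 12.5) of those tested, an odds ratio of 0.973 (0.471 to 2.33, adjusted exact p = 1). The strongest were at dpy-3 (127), dpy-10 and dpy-2 (107, a shared peak) and dpy-8 (74.9). Of the 19 epidermal transcription factor genes tested, grh-1 alone had one (80.8, odds ratio 0.856, adjusted exact p = 1), with both the core and GAGAGA at its summit.

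Lists for other tissues gave no call. Body wall muscle had 2 of 22, lim-8 (109) and deb-1 (68.8), with an odds ratio of 1.54 and adjusted exact p = 0.676. The pharynx list had 3 of 42, pqn-51 (136), pqn-21 (70.1) and pqn-71 (53.8), with 1.19 and adjusted exact p = 0.939, and 0.679 with replicate 1's own regions. This list took in all pqn genes by symbol alone, and the 3 bound members are pqn genes. The neuronal list had 3 of 31, mec-7 (100.9), unc-4 (96.2) and snb-1 (49.1), with 1.65 and adjusted exact p = 0.688. The mec-7 and unc-4 peaks ranked 74 and 98 in replicate 1, against rank 14521 and no candidate in replicate 2, and the odds ratio was 0.268 with replicate 2's own regions and 2.52 with replicate 1's. Intestinal genes had 0 of 15, which allows up to 21.8%, and germline and oocyte genes had 0 of 40, which allows up to 8.81% (adjusted exact p = 1 and 0.414). With replicate 1's own regions the germline share was 5.26%.

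Signalling and regulator lists gave no call either. Wnt signalling had 2 of 21, hmp-2 and mig-5 (59.7), with 1.62 and adjusted exact p = 0.676, and 0.846 with replicate 2's own regions. Axon guidance and cell migration had 2 of 35, mig-15 (50.8) and slt-1 (50.2), with 0.934 and adjusted exact p = 1, and 0.267 with replicate 1's own regions. Homeobox genes had 2 of 61, unc-4 and zag-1 (47.3), with 0.521 and adjusted exact p = 0.858. The homeobox odds ratio was 0.141 with replicate 2's own regions and 0.256 without the peaks in runs. Nuclear hormone receptors had 4 of 176, nhr-14 (82.2), nhr-3 (57.8), unc-55 (50.1, no candidate in replicate 2) and nhr-1 (48.8), with 0.354 (0.155 to 1.02, exact p = 0.0260, adjusted p = 0.0987). With replicate 2's own regions that odds ratio was 0.577 (adjusted exact p = 0.598). Heat shock and stress genes had 4 of 26, hsp-60 (117), atfs-1 (76.8), hsp-110 (57.4) and hsp-1 (52.6), with 2.81 (1.12 to 8.53, adjusted exact p = 0.223), and 4.56 (adjusted p = 0.0564) with replicate 1's own regions. Histone genes had 2 of 24, his-67 and his-68, which share a peak of signal 59.3 (1.40, adjusted exact p = 0.890), and with replicate 2's own regions the odds ratio was 0.286.

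No IDR summit lay in the promoter window of any of the 13 genes chosen in advance, several of which act with blmp-1 in timing or epidermal development. Of all 19985 protein-coding genes 672 had such a summit, so its absence at so few genes shows no depletion. The epidermal receptor gene nhr-25 held 2 IDR summits in its body, the stronger at X 13009042 (signal 71.4, rank 348). That summit lay 549 bp downstream of the start, just past the window's limit of 500 bp. The netrin receptor gene unc-5 held 1 in its body at IV 5514770 (signal 63.0, rank 464). Among the others, nhr-23, a molting regulator, had the best pooled candidate in window or body, of rank 925 in its body (signal 44.1). Outside its window, an IDR summit at I 7212129 lay 2616 bp upstream of the nhr-23 start (signal 152, rank 75). It lay in a coding exon, within the gene C01H6.4, and 2263 bp upstream of a nearer start, that of C01H6.3. Both of these genes were chosen after their values were seen. The IDR summit nearest to the lin-4 start lay 2977 bp away. In window or body, the best pooled ranks were 3184 at lin-29, 3200 at let-7, 3327 at bed-3, 4138 at elt-1, 4530 at dre-1, 4710 at lin-28, 6688 at elt-3 and 19574 at unc-119. The genes lin-4 and blmp-1 had no pooled candidate. Within a single replicate, lin-29 reached rank 371 in replicate 2 (4073 in replicate 1), nhr-23 rank 382 in replicate 2 (898 in replicate 1) and bed-3 rank 747 in replicate 1 (6479 in replicate 2). The named miRNA genes mir-48 and mir-241 had pooled ranks 6028 and 13104, and mir-84 had none.

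The IDR list is too short to show whether the transgene's own loci stand out. An even spread would give 0.371 IDR peaks within 20000 bp of blmp-1 and 0.378 within that distance of unc-119. Within 20000 bp of blmp-1 lay 0 IDR peaks, 1 pooled candidate, 0 candidates of replicate 1 and 5 of replicate 2, where an even spread of the pooled list would give 13.6. The pooled candidate, at I 10417684, had rank 14709. Around unc-119, the marker gene of the strain, lay 1 IDR peak at III 10911416 (signal 53.1, rank 633), 44 bp upstream of cut-6. The pooled list had 18 candidates there, replicate 1 had 21 and replicate 2 had 13, where an even spread would give 13.8 in each.

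IDR peaks lay near noncoding RNA genes more often than the other candidates did. This comparison was fixed in advance as a check for signal that many ChIP experiments show at highly transcribed RNA genes, whatever the factor. Such signal could not be told apart from BLMP-1 binding here. Within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene lay 68 summits, 8.07% (6.32 to 10.1), against 1.75% (odds ratio 4.94, 3.82 to 6.45, two-sided Fisher's exact p = 1.49e-23). Of these, 49 were nuclear (odds ratio 3.59, 2.68 to 4.89). Among nuclear peaks, 28 lay near tRNA genes (3.401, 2.34 to 5.11) and 20 near snoRNA genes (4.37, 2.80 to 7.09), and 0 of 818 near rRNA genes, which allows up to 0.450%. The snRNA share was 0.244% against 0.148% (exact p = 0.350).

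The genes with the most IDR summits in window or body were mitochondrial: CYTB and ND5 with 7 each, COX1 and ND2 with 6 each, and ATP6 with 5. Windows of neighbouring mitochondrial genes overlap, so the same summit counted for several genes and these counts do not single out a gene. The nuclear genes kin-20, pqn-41 and unc-4, chosen after their values were seen, tied with ATP6 at 5. The 25 mitochondrial IDR peaks occupied 21 distinct regions, which covered 59.9% of the 13794 bp genome, with a median signal of 289. The mitochondrial genome holds 0 copies of the core, which lay at 15.5% (13.1 to 18.2) of nuclear summits.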

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

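The alternatives with nuclear chromosomes only and without the runs found in replicate 1 alone were chosen after the results were seen. Of 327 alternative values over 36 results, 264 were unchanged in kind: tested results kept their direction and their side of the threshold, counts stayed within 1.5 times, and shares stayed within the reach of their 95% interval. The promoter share, the core sequence, the noncoding RNA share and the apical matrix list kept theirs under each alternative run for them. With one replicate's own regions the promoter odds ratio ranged from 1.72 to 1.73, the core from 8.88 to 9.51, noncoding RNA genes from 4.92 to 5.44, and the lists that pass from 2 to 3. The X share ranged from 1.07 to 1.21, and was 1.19 with nuclear chromosomes only. Unknown depth limits any comparison of signal between replicates. The intestine and germline lists had no bound member in the IDR list, so their odds ratios rest on the continuity correction. With one replicate's own regions germline ranged from 0.154 to 0.906, and it was 0.899 with the 5000 bp window.

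The IDR set of 422 strongest peaks is smaller by construction, and it gave 309 bound genes and 1 list. The 5000 bp window, wider by construction, gave 1090 genes and 5 lists, and the nearest start alone gave 1 list. Replicate sharing was 45.1% in either direction with reciprocal overlap and 46.98% with summits within 100 bp. It was 41.99% and 42.1% ranked by q value, where 4.84% of replicate 2's regions tie at the ceiling and signal orders them, 59.9% and 59.6% with the list length halved, and 41.7% and 41.6% with it doubled. Except where construction is named, the cause was not tested.

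The odds ratios that turned to the other side of 1 belong to results that did not pass the test in the original setting or the alternative. With the 422 strongest peaks they were other positions 1.06, GATA 0.994, E-box 0.900, cuticle collagens 1.44, epidermal transcription factors 1.93, intestine 1.12 (0 bound) and histones 0.705. With one replicate's own regions, other positions ranged from 1.01 to 1.19, GATA from 0.991 to 1.19, epidermal transcription factors from 0.960 to 1.06, pharynx from 0.679 to 0.996, neuronal from 0.268 to 2.52, Wnt from 0.846 to 1.92 and histones from 0.286 to 1.63. The 1000 bp window gave other positions 1.14, cuticle collagens 1.26, body wall muscle 0.908, intestine 1.19 (0 bound), pharynx 0.617 and homeobox 1.03. The 5000 bp window gave cuticle collagens 1.26, epidermal transcription factors 1.26, pharynx 0.546, axon guidance 1.02 and histones 0.719. The nearest start gave cuticle collagens 1.44, epidermal transcription factors 1.26, axon guidance 1.37 and histones 0.985. All genes as background gave cuticle collagens 1.01, epidermal transcription factors 1.06, pharynx 0.937, axon guidance 1.34 and histones 0.821. Matching on G+C content gave E-box 0.852. The cause was not tested.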

Other observations

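The tests of mitochondrial coverage, of core copies in the mitochondrial genome, of GAGAGA outside promoter windows and of coding exons in runs were chosen only after the results were seen, and the rule that fewer than 6 loci decide nothing was set after the odds ratio in runs was seen. Several nuclear loci carried groups of IDR peaks, described here after their values were seen. The X chromosome cluster of lpr-3, lpr-4, lpr-5 and lpr-6, genes for lipocalin-related matrix proteins, held 5 peaks from 11057341 to 11067543, with a highest signal of 351. The kinase gene kin-20, a homologue of the clock kinase Doubletime, held 5 peaks from X 15274196 to 15277906, with a highest signal of 254. On chromosome III, pqn-41 held 5 peaks from 1921559 to 1926600, with a highest signal of 119.4. Upstream of bcl-11 on chromosome V lay 4 peaks from 6351289 to 6354386.

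The collagen genes dpy-10 and dpy-2 shared 3 peaks from II 6712418 to 6714086, with a highest signal of 107, although the collagen list as a whole did not pass. Another group of 3 lay nearest to F23H12.3, F23H12.5 and the collagen gene sqt-3, from V 12349555 to 12357837, with a highest signal of 111. None of its summits lay in the promoter window of sqt-3. A group of 4 lay near osr-1 and sem-2 from I 5203426 to 5211168, with a highest signal of 99.1. Of the 164 strongest nuclear peaks 28.7% (21.9 to 36.2) had the core, against 7.98% (4.31 to 13.3) of the 163 weakest (odds ratio 4.64, 2.35 to 8.64, Fisher's exact p = 1.44e-06). GAGAGA had no such difference that passed the test, with 26.8% and 28.2% (odds ratio 0.933, 0.576 to 1.51, exact p = 0.805).

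The mitochondrial genome held 25 IDR peaks, among them the strongest of the list. Binding through exact copies of the core was argued against, since the mitochondrial genome holds 0 of them. For the same reason the core count at the summits, 0, decides nothing, and binding through other sequences stays open. A high copy number of mitochondrial DNA may account for the peaks, since the regions covered 59.9% of the genome, but that coverage was known before the test was chosen. The design has a single group, so no difference between groups could be tested.

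GAGAGA lay at 29.9% of IDR summits against 7.002% of other candidates. Base composition as the whole cause was argued against, because the odds ratio against candidates matched on G+C content was 2.99 (2.54 to 3.51), above the limit of 1.5 set for that explanation. Lying in an annotated promoter window was argued against as the whole cause. Outside such windows GAGAGA lay at 29.9% of 351 nuclear summits against 6.37% of other candidates (odds ratio 6.27, 4.96 to 7.96). Promoter peaks against the rest gave 1.06 (0.781 to 1.42). The windows rest on annotated gene starts, so promoters beyond them or without annotation stay open. Whether promoter peaks with GAGAGA enter the list without the core stays open, since its odds ratio at summits with against without the core was 0.696 (0.456 to 1.08). Open chromatin enriched in many ChIP experiments could give the same picture, and that was not tested, because no other factor's peaks were used here.

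Nuclear regions at the top of one replicate alone numbered 397 in replicate 1 and 394 in replicate 2. Noise in rank stays open: 76.6% and 73.4% of them were candidates in the other replicate, between the limits of 50% and 80% set for that explanation. Promoter signal without the core in one replicate stays open too, with an odds ratio of the core of 0.779 (0.475 to 1.28) between the sets. For the 23 regions in runs at unc-4, dpy-20 and lin-15, extra copies of these sequences in the replicate 1 sample may be a source, which stays open: the odds ratio of coding exons there was 79.8, but the regions are neighbours at 3 loci, picked because they lie in runs, so it decides nothing. The genes dpy-20 and lin-15 are widely used as transformation markers, but the labels name blmp-1 and unc-119 only, no sequence reads were analysed here, and the single replicate 1 regions at ttr-39, mec-7 and unc-55, for which the same source stays open, were not tested.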
